A study of Mus musculus with 11 samples.

How the data were processed

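The libraries came from trigeminal ganglion neurons of mice, the sensory neurons of the face and mouth. Neurons whose endings had taken up the retrograde tracer DiI were sorted by fluorescence, and poly(A)-selected RNA was sequenced as single-end reads, per the labels' protocols. Tumour-bearing mice carried MOC1, a mouse oral squamous cell carcinoma line, and the others were sham controls. The labels give 3 MOC1 female, 3 MOC1 male, 3 sham female and 2 sham male libraries, 11 in all.

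Each deposited file held the authors' raw read counts per gene from STAR, strand-specific and not normalized, per the file headers and the whole-number values. Reads were trimmed with Trimmomatic 0.35 and aligned with STAR 2.7.1a to GRCm38 (mm10), and RSEM is named as well, per the submitters' processing notes. The annotation release is not given in the sources used here. The files list 55401 genes, with identifier, name and position, and 4 totals that name no gene (unmapped, multimapping, no feature and ambiguous reads). Those 4 held between 18.7% and 21.5% of all counts and were left out of library sizes and tests. Reads that map to several places are not counted to a gene in such files, so genes with near-identical copies, such as Hspa1a and Hspa1b, are uncertain. Counts are strand-specific, so antisense partners were counted apart. Of the gene identifiers, 55141 matched the reference annotation supplied with the data.

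Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups of condition and sex, which left 16817 genes. Libraries were scaled by TMM. The main comparison was a quasi-likelihood F test of MOC1 against sham with sex as an additive term, with Benjamini-Hochberg adjustment and a threshold of 0.05. A 4-group fit with one shared estimate of the spread gave the comparisons within females and within males and the sex by tumour interaction. Standard errors (SE) of log2 fold changes were taken as the size of the change over the square root of F. Levels are CPM after TMM scaling, as mean ± SD, and list shares are summed CPM of all gene counts without TMM. For Trpv1, Calca and Ngfr, which the series design names, log2 CPM was also compared by a two-sided exact permutation test over all 462 regroupings of the 11 libraries, adjusted over the 3 genes. The smallest p this test allows is 0.00216. The same test was used for library measures.

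Before the data were examined, 28 gene lists and 11 lists of cell type markers were fixed, 39 in all, with 988 of 989 names found. Lists were tested with camera (limma 3.58.1, voom values) at a preset correlation of 0.01, with an estimated correlation and fry as companions. List means and medians come from the same voom values, and medians under other scalings or without the 3 libraries left out together from edgeR. A camera p compares a list with the other genes. A fry p asks whether a list's genes move one way. Names in the text follow a rule also fixed beforehand. It takes the 12 genes with the smallest p in each direction with a mean of at least 1 CPM, Trpv1, Calca and Ngfr, and up to 4 members of each list that passed or that holds a called gene. It takes up to 2 members of other lists, the 5 leading genes per direction within each sex, and the genes that check the sex labels. Unnamed gene models and pseudogenes are skipped among the leading genes. Some genes that the rule takes are not reported here.

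Alternatives were DESeq2 1.42.0, its size factors, no low-count filter, a filter of 1 CPM in 5 libraries, voom with quality weights, each library left out in turn, the replicate number as a block, no sex term, a surrogate variable (sva 3.50.0), a glial marker covariate, total-count scaling, and removal of mitochondrial, haemoglobin and ribosomal genes. The glial marker covariate was the log2 share of the satellite glia and Schwann cell lists together, and the latter holds Ngfr. After the data had been seen, scaling to the pan-neuronal list, scaling to the satellite glia list and removal of 3 libraries were added. The 3 are sham female 1, with high endothelial counts, and MOC1 female 3 and MOC1 male 2, which lie farthest out on PC1 and PC2 of log2 CPM. MOC1 female 2, which lies farthest out on PC3, was left out only in its turn.

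The tests were run first on simulated counts for the same 16817 genes, with 200 genes changed. In the simulated MOC1 against sham comparison, edgeR recovered 31.3% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 66.7% of those changed 4-fold, with 4 false calls. For the interaction edgeR recovered 0% at 1.5-fold, 19.4% at 2-fold and 48.5% at 4-fold. In the simulated MOC1 against sham comparison DESeq2 made 44 false calls and voom with quality weights 3, so the larger counts from DESeq2 need caution. No pair of libraries within a group agreed within sampling noise, since chi-square per degree of freedom lay between 13.9 and 42.4. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these samples, which may be technical. No molecular identifiers are recorded, so counts are reads and not molecules.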

Results

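Gene expression was measured in DiI-labelled trigeminal ganglion neurons from 6 libraries of MOC1 tumour-bearing mice and 5 of sham mice. Each library held between 10757400 and 16703800 counts in genes. MOC1 libraries averaged 14408500 ± 1916880 (SD, n = 6) and sham libraries 16369500 ± 497609 (SD, n = 5), a difference with an adjusted p of 0.0361 in an exact permutation test. The genes detected per library ranged from 14180 to 19078. In a principal component analysis of log2 CPM, single MOC1 libraries stood apart. MOC1 female 3 lay at 178.8 on PC1 (26.6% of the variance), where the others lay between -43.6 and 18.0. MOC1 male 2 lay at -133.1 on PC2 (15.4% of the variance), where the others lay between -15.2 and 35.5. MOC1 female 2 lay at 103.7 on PC3, above all other libraries. These 3 libraries had the fewest genes detected, at 14180, 15327 and 16043 in that order, against 16420 or more in the others. Whether this sets them apart was not tested. Without each of these 3 in turn, 1089, 1129 and 816 genes differed between MOC1 and sham.

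The libraries differed in the markers of satellite glia, the cells that wrap sensory neuron bodies. Their 16 markers summed to 5124 ± 1052 CPM in MOC1 libraries (SD, n = 6) and 10964 ± 780 CPM in sham libraries (SD, n = 5). The arms did not overlap (3671 to 6640 against 10081 to 12208, adjusted p = 0.00676, exact permutation test). The 20 pan-neuronal genes summed to 13564 ± 589 CPM in MOC1 and 11183 ± 1121 CPM in sham libraries, again without overlap (adjusted p = 0.00676, exact permutation test). The summed fibroblast markers stood at 120 ± 12.5 CPM in MOC1 and 190 ± 44.6 CPM in sham libraries (adjusted p = 0.00676, exact permutation test). Of that sum Col1a2 alone held 33.3 and 79.8 CPM after TMM scaling. Macrophage markers stood at 60.4 ± 14.1 and 75.4 ± 38.5 CPM (adjusted p = 0.534, exact permutation test). Squamous epithelium and tumour markers stood at 455 ± 42.2 and 438 ± 28.4 CPM (adjusted p = 0.532, exact permutation test). Most of that sum was Cdh1 alone, and 6 of the 19 markers passed the low-count filter. No library held more than 1.97 CPM of Dsg3 or 1.31 CPM of Epcam after TMM scaling. The mitochondrial share of counts was 2.89% ± 0.311 in MOC1 and 3.65% ± 0.615 in sham libraries (adjusted p = 0.0271, exact permutation test).

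**Figure D1:**
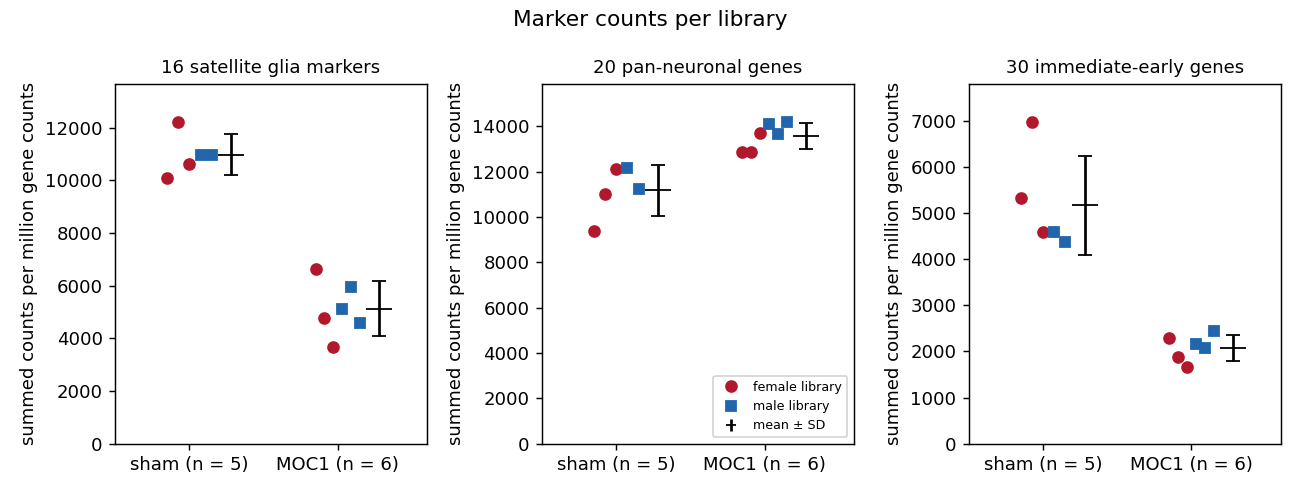
Summed CPM of all gene counts for satellite glia markers, pan-neuronal genes and immediate-early genes in each library (circles female, squares male), with the mean and SD of 5 sham and 6 MOC1 libraries. Satellite glia markers lie between 3671 and 6640 in MOC1 and between 10081 and 12208 in sham libraries.

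The series asks how a tumour changes the neurons that innervate it. Of 16817 genes tested, 1113 differed between MOC1 and sham, 394 higher and 719 lower in MOC1. Pappa, a protease that cleaves insulin-like growth factor binding proteins, rose 6.28-fold, from 4.55 ± 0.838 to 29.6 ± 9.61 CPM (log2 fold change 2.65 ± 0.23 SE, adjusted p = 2.63e-06). Alkal2, a ligand of the ALK receptor, rose 4.15-fold, from 7.97 ± 1.70 to 33.8 ± 6.39 CPM (log2 2.05 ± 0.20, adjusted p = 4.74e-06). Trpa1, the irritant-sensing channel of nociceptors, rose 1.79-fold, from 242 ± 22.8 to 435 ± 62.6 CPM (log2 0.84 ± 0.10). The neuropeptide precursor Vgf (log2 1.07 ± 0.14), the neurotrophin Bdnf (0.94 ± 0.13) and the synaptic pentraxin Nptx2 (0.95 ± 0.13) rose as well. Serpinb1a rose by 1.14 ± 0.16, Onecut2 by 0.74 ± 0.10, Sez6l2 by 0.64 ± 0.09, Fstl1 by 0.51 ± 0.05 and the axon guidance receptor Robo2 by 0.50 ± 0.07. Pappa lies on chromosome 4 (65124174 to 65357509, GRCm38), Alkal2 on chromosome 12 (30884322 to 30893854) and Trpa1 on chromosome 1 (14872648 to 14918862).

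Among the called genes, a gain of at least 2-fold was seen for 24 and a loss of that size for 313. With the libraries scaled to the pan-neuronal list, 29 genes were higher and 2095 lower, and the median of all genes moved to -0.30. With scaling to the satellite glia list, 10049 were higher and 49 lower, with a median of 1.08. Of the 12 risers with the smallest p, 10 were still called with pan-neuronal scaling, and Robo2 (log2 0.22) was among those that were not. With the glial marker share, which does not overlap between the arms, as a covariate, no gene was called by edgeR, although 1151 had an unadjusted p under 0.05.

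**Figure D2:**
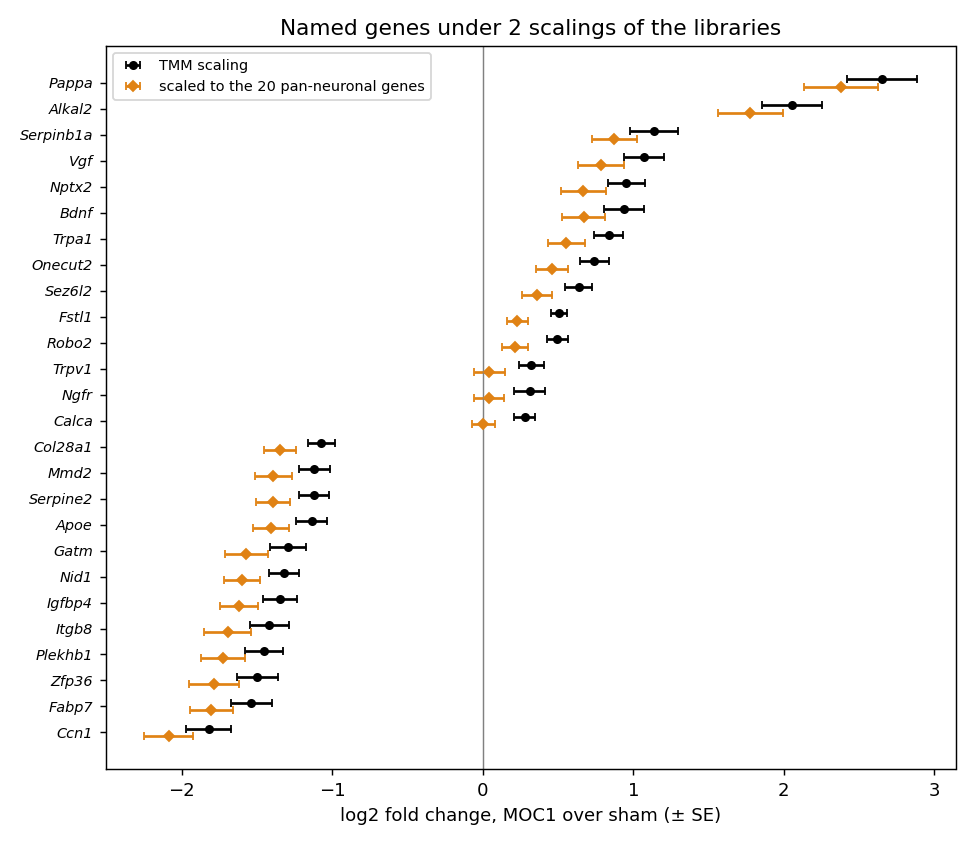
Log2 fold change of MOC1 over sham with its SE for 23 of the 24 genes with the smallest p and for Trpv1, Calca and Ngfr, with TMM scaling (black circles) and with scaling to the pan-neuronal genes (orange diamonds). Calca moves from 0.28 to 0.00, and Pappa from 2.65 to 2.38.

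In the satellite glia list, 15 of 16 markers fell and 1 did not pass, and all 16 passed when adjusted over the list alone. Fabp7, a glial fatty acid binding protein, fell by 1.54 on the log2 scale (SE 0.14, from 781 ± 142 to 268 ± 60.1 CPM, adjusted p = 2.84e-06). Apoe, the lipid carrier, fell by 1.14 (SE 0.10) and Sostdc1 by 1.37 (SE 0.13). The list's adjusted p was 8.49e-32 with camera and 0.0334 with an estimated correlation. The other leading losses were Nid1, a basement membrane protein (log2 -1.32 ± 0.10), Ccn1 (-1.82 ± 0.15), Col28a1 (-1.07 ± 0.09), Igfbp4 (-1.34 ± 0.11), Plekhb1 (-1.45 ± 0.13), Serpine2 (-1.12 ± 0.10), Itgb8 (-1.42 ± 0.13), Mmd2 (-1.12 ± 0.10) and Gatm (-1.29 ± 0.12). In the Schwann cell list, which shares members such as Sox10 with the satellite glia list, 6 of 19 fell and 2 rose (8 and 3 adjusted over the list alone), among them Cnp (log2 -0.53 ± 0.09) and Mal (-0.92 ± 0.17). Its adjusted p was 0.0053, and the adjusted p = 0.0723 with an estimated correlation. Scaled to the satellite glia list, Col28a1, Cnp and Mal had log2 changes above 0, where the median of all genes was 1.08.

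In the pan-neuronal list 11 of 20 rose and none fell, with a median log2 change of 0.29, or 15 adjusted over the list alone, including Tubb3 (0.39 ± 0.08), Prph (0.29 ± 0.06), Avil (0.29 ± 0.06) and Elavl4 (0.33 ± 0.07). Its camera adjusted p was 5.66e-14, and the adjusted p = 0.0506 with an estimated correlation. In the list of neuropeptides and their processing 6 of 22 rose (14 adjusted over the list alone), with the prohormone convertase Pcsk1 (0.75 ± 0.17) and the granin Scg2 (0.33 ± 0.08) beside Vgf and Calca, and the list held with an estimated correlation (adjusted p = 0.0144). In the list of sodium channels and their partners 3 of 15 rose (7 adjusted over the list alone). They were the channel gene Scn9a (0.36 ± 0.07) and Fgf12 (0.37 ± 0.08) and Fgf13 (0.24 ± 0.06), whose products bind such channels, while Scn8a (0.39 ± 0.12) did not pass (list adjusted p = 0.0204 with an estimated correlation). In the list of calcium channels and their subunits 3 of 17 rose (6 adjusted over the list alone), with Cacna2d1 (0.48 ± 0.07), Cacnb3 (0.35 ± 0.07) and Cacna1b (0.36 ± 0.08), with Cacna1h at 0.43 ± 0.13 (list adjusted p = 0.0439 with an estimated correlation). In the synaptic vesicle list 9 of 30 rose (20 adjusted over the list alone), among them Syp (0.36 ± 0.06) and Bsn (0.44 ± 0.11), with an adjusted p of 0.0334 with an estimated correlation. In the list of ligand-gated, acid-sensing, HCN and mechanosensitive channels 5 of 40 rose and P2rx7, an ATP-gated channel, fell from 21.5 ± 3.83 to 10.8 ± 2.94 CPM (10 and 1 adjusted over the list alone). Among the risers were Piezo2 and Gabbr1 (0.27 ± 0.06), and the list's adjusted p was 0.0268 with an estimated correlation. Scaled to the pan-neuronal list, the medians of the sodium channel (-0.04), synaptic vesicle (-0.04) and ligand-gated (-0.02) lists were below 0 and those of the calcium channel (0.02) and neuropeptide (0.08) lists above 0. No gene of the sodium channel, calcium channel or synaptic vesicle lists was then called by edgeR, while 1 neuropeptide gene was higher and 1 lower, and 1 gene of the ligand-gated list was lower. These groups moved in the libraries with the lower satellite glial share.

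The lists of sensory neuron classes, TRP channels and potassium channels passed camera and lost the call with an estimated correlation. In the peptidergic list 4 of 15 rose (10, with 1 lower, adjusted over the list alone). They were Trpa1, Scg2, Calca and Trpv1 (camera adjusted p = 2.34e-05, adjusted p = 0.0649 with an estimated correlation). In the nonpeptidergic list 2 of 17 rose (4 adjusted over the list alone), both receptors of itch-related cytokines, Il31ra (1.35 ± 0.24) and Osmr (0.77 ± 0.13), with Cysltr2 at 0.99 ± 0.31 and P2rx3 at 0.25 ± 0.08 not passing (camera adjusted p = 8.47e-04, adjusted p = 0.198 with an estimated correlation). In the cold and low-threshold list of 9, Piezo2 rose (0.26 ± 0.07), with 4 higher and 1 lower adjusted over the list alone, while Trpm8 (0.49 ± 0.16), Gpm6a (-0.48 ± 0.16) and Cdh8 (0.49 ± 0.18) did not pass (camera adjusted p = 0.0234, adjusted p = 0.159 with an estimated correlation). Of 18 genes of myelinated neurons, Cntnap2 rose (0.41 ± 0.08) and Ntrk2 fell (-0.79 ± 0.12), as they did adjusted over the list alone, with Nefm at 0.27 ± 0.10 and Scn4b at 0.31 ± 0.11 (camera adjusted p = 0.0234, adjusted p = 0.585 with an estimated correlation). In the TRP channel list 2 of 17 rose (3 adjusted over the list alone), with Trpc6 at 0.34 ± 0.14 (camera adjusted p = 0.00695, adjusted p = 0.138 with an estimated correlation). In the list of potassium channels and their subunits 3 of 41 rose (4, with 1 lower, adjusted over the list alone), Kcnh7 (0.47 ± 0.08), Kcnab2 (0.33 ± 0.06) and Kcnma1 (0.42 ± 0.11), and the glial channel Kcnj10 fell (-1.35 ± 0.19) (camera adjusted p = 0.00508, adjusted p = 0.0506 with an estimated correlation). Scaled to the pan-neuronal list, 1 peptidergic gene was higher and 2 lower, 2 nonpeptidergic genes higher and 1 lower, and 1 TRP channel gene higher and 2 lower. None was then higher in the cold and low-threshold, myelinated and potassium channel lists, with 1, 4 and 2 lower. Il31ra and Osmr kept their calls with pan-neuronal scaling, at 1.08 and 0.48, whereas Piezo2 stood at -0.02, Fgf13 at -0.04 and Gabbr1 at -0.01.

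Of 29 immediate-early genes, the first to respond to cell stimulation, 20 fell and none rose, and 26 fell when adjusted over the list alone. Fos fell by 1.51 on the log2 scale (SE 0.15) and Nr4a1 by 1.02 (SE 0.10), beside Ccn1 and the mRNA-decay factor Zfp36, which fell from 255 ± 59.1 to 91.0 ± 14.2 CPM. The list's adjusted p was 4.64e-26 with camera and 0.0334 with an estimated correlation. The list summed to 2084 ± 280 CPM in MOC1 (SD, n = 6) and 5171 ± 1072 CPM in sham (SD, n = 5), in the same libraries in which satellite glia markers were low and high. Among 21 heat shock genes 5 fell and 1 rose (10 and 1 adjusted over the list alone), with Hspa1a at -2.42 ± 0.30, Hspa1b at -2.38 ± 0.32, Dnajb1 at -1.68 ± 0.26 and Cryab at -1.42 ± 0.22 (camera adjusted p = 4.20e-05, adjusted p = 0.138 with an estimated correlation). In the unfolded protein response list 5 of 31 fell (6 lower and 1 higher adjusted over the list alone), among them Ppp1r15a (-0.93 ± 0.12), Hspa5 (-0.43 ± 0.08), Hsp90b1 (-0.39 ± 0.07) and Phgdh (-1.38 ± 0.28) (camera adjusted p = 8.97e-04, adjusted p = 0.138 with an estimated correlation). Scaled to the satellite glia list, the median of the immediate-early genes was -0.07, with 3 genes higher and 2 lower.

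In 4 further lists most members did not pass, and each list lost its camera call with an estimated correlation. In the interferon-stimulated list 8 of 41 fell (15 lower and 1 higher adjusted over the list alone), including Cxcl10 (-1.84 ± 0.23), Irf1 (-1.43 ± 0.21), Irgm1 (-1.42 ± 0.22) and Gbp3 (-1.11 ± 0.22) (camera adjusted p = 1.81e-06, adjusted p = 0.156 with an estimated correlation). In the list of MHC class I presentation and checkpoint ligands 5 of 26 fell and 1 rose (8 and 2 adjusted over the list alone), with H2-Q4 at -1.70 ± 0.32, B2m at -0.79 ± 0.16, Calr at -0.31 ± 0.08 and Tap1 at -0.82 ± 0.23 (camera adjusted p = 0.00244, adjusted p = 0.325 with an estimated correlation). The MHC list's median was -0.69 in females (camera adjusted p = 3.99e-04) and -0.15 in males (camera adjusted p = 0.255). With an estimated correlation the camera adjusted p values were 0.239 and 0.757. B2m reached 516 CPM in a sham female library, while male libraries of both arms lay between 159 and 214 CPM. Of 25 cholesterol synthesis genes 7 fell (8 adjusted over the list alone), led by Cyp51 (-0.77 ± 0.07), Hmgcs1 (-0.42 ± 0.06), Msmo1 (-0.48 ± 0.07) and Insig1 (-0.73 ± 0.11) (camera adjusted p = 9.42e-06, adjusted p = 0.107 with an estimated correlation). Of 7 mitochondrially encoded genes 3 fell (6 adjusted over the list alone), mt-Nd2 (-0.47 ± 0.09), mt-Cytb (-0.36 ± 0.10) and mt-Nd4 (-0.34 ± 0.10), with mt-Co1 at -0.26 ± 0.08 (camera adjusted p = 2.22e-04, adjusted p = 0.198 with an estimated correlation). The medians of the interferon (0.37), MHC (0.69), unfolded protein (0.80), heat shock (0.90), mitochondrial (0.85) and cholesterol (0.95) lists were above 0 with satellite glia scaling. That scaling shifts nearly every gene upward, and these medians lay below the median of all genes (1.08).

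Other lists moved in part or not at all. Of 31 axon injury genes Bdnf was among 2 that rose and 4 fell, including Socs3 (-1.20 ± 0.13), Jun (-1.06 ± 0.14) and Atf3 (-1.01 ± 0.14), with the same counts adjusted over the list alone (camera adjusted p = 0.577). Of 12 neurotrophin and GDNF-family genes Bdnf rose, and Ntrk2 and Sort1 (-0.48 ± 0.09) fell, with a mean of -0.10 and a median of 0.19, and 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.05, adjusted p = 0.138 with an estimated correlation). Of 47 axon guidance genes 5 rose, among them Robo2, Sema4f (0.42 ± 0.10) and Slit1 (0.32 ± 0.09), and Efnb1 fell (-0.92 ± 0.15), with 7 higher and 1 lower adjusted over the list alone. Its mean (-0.18) and median (-0.08) were below 0 and camera's direction was up (adjusted p = 0.307). Scaled to the pan-neuronal list, 0 axon guidance genes were higher and 4 lower. Of 45 cytokine, chemokine and receptor genes 2 rose, Il31ra and Osmr, and 6 fell, including Cxcl10 and Il1rap (-1.36 ± 0.30), or 2 and 8 adjusted over the list alone (camera adjusted p = 0.263). In the CGRP and calcitonin-family list, Calca was the 1 of 7 that rose, as it was adjusted over the list alone, while Calcrl (-0.92 ± 0.46) and Ramp2 (-0.54 ± 0.28) did not pass (camera adjusted p = 0.826). Rps26 (0.41 ± 0.12) was the only call among 79 ribosomal protein genes, where Rpl41 (-0.34 ± 0.12), Rplp1 (-0.31 ± 0.13) and Rplp0 (-0.18 ± 0.08) did not pass, and adjusted over the list alone 0 passed in edgeR (camera adjusted p = 0.777). No gene passed in edgeR, over all genes or adjusted over the list alone, in the opioid and cannabinoid list (camera adjusted p = 0.0696, Cnr1 0.37 ± 0.14, Oprm1 0.34 ± 0.16), the oxidative phosphorylation list (0.0587, Ndufa9 0.22 ± 0.09, Atp5e -0.34 ± 0.15) or the proliferation list (0.045, and 0.239 with an estimated correlation, Mcm6 -0.83 ± 0.38, Prc1 -0.85 ± 0.40, Bub1b 0.69 ± 0.37).

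Among markers of other cells, 2 of 18 endothelial and mural genes fell, Cspg4 (-1.48 ± 0.31) and Cldn5 (-1.91 ± 0.56), or 6 adjusted over the list alone, with Emcn at -1.69 ± 0.52 and Tek at -1.34 ± 0.49 (camera adjusted p = 0.0291, adjusted p = 0.607 with an estimated correlation). The first sham female library held 1828 CPM of these markers, against at most 481 CPM in the other sham libraries. Without sham female 1, MOC1 female 3 and MOC1 male 2 the edgeR median of the endothelial and mural list went from -1.21 to -0.08, with 1 gene lower. Of 14 fibroblast genes Col1a2 fell (-1.28 ± 0.14), also adjusted over the list alone, and Lum (-1.93 ± 0.79), Apod (-0.58 ± 0.29) and Col3a1 (-0.77 ± 0.40) did not pass (camera adjusted p = 0.235). The list's edgeR median turned from -0.36 to 0.25 without sham female 1, MOC1 female 3 and MOC1 male 2. No macrophage gene passed (camera adjusted p = 0.89, Lyz2 -1.22 ± 0.54, Cd74 -0.75 ± 0.37), and that list's mean (-0.01) and median (-0.02) lay below 0 while camera's direction was up. Of 4 lymphocyte genes none passed over all genes and 1 fell adjusted over the list alone (camera adjusted p = 0.126, Ighm -0.94 ± 0.30). No gene passed, by either adjustment, among the neutrophil and mast cell (0.777, Ltf -2.13 ± 1.26), erythrocyte (0.89, Alas2 -1.73 ± 1.05, Hbb-bs -1.12 ± 0.99), squamous epithelium and tumour (0.691, mean -0.20 and median -0.06 with camera's direction up, and an edgeR median of 0.06), skeletal muscle (0.615, Myh2 0.69 ± 1.14) and brain (0.535, Aqp4 -0.39 ± 0.15, Slc1a2 -0.27 ± 0.30) lists, each with its camera adjusted p.

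The series names Calca, Trpv1 and Ngfr for a comparison between the arms. Calca, which encodes the neuropeptide CGRP, rose 1.21-fold, from 1019 ± 60.5 CPM (SD, n = 5) to 1240 ± 108 CPM (SD, n = 6), with a log2 change of 0.28 ± 0.07 SE and an adjusted p of 0.0176. Trpv1, the heat and capsaicin receptor, rose 1.25-fold, from 190 ± 16.7 to 246 ± 46.2 CPM (log2 0.32 ± 0.08, adjusted p = 0.0195). Ngfr, the low-affinity neurotrophin receptor, stood at 370 ± 70.4 and 461 ± 25.8 CPM (log2 0.31 ± 0.10) and did not pass over all genes (adjusted p = 0.0849). Exact permutation tests gave adjusted p values of 0.00649 for Calca, 0.0303 for Trpv1 and 0.00649 for Ngfr. Scaled to the pan-neuronal list, the log2 changes were 0.00 ± 0.08 for Calca, 0.04 ± 0.10 for Trpv1 and 0.04 ± 0.10 for Ngfr, and none passed. Without the second MOC1 female, the first sham male or the third sham male library, the adjusted p was 0.0523, 0.0541 and 0.0899 for Calca and 0.0616, 0.0581 and 0.102 for Trpv1, and without the second sham female library it was 0.0264 for Ngfr.

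**Figure D3:**
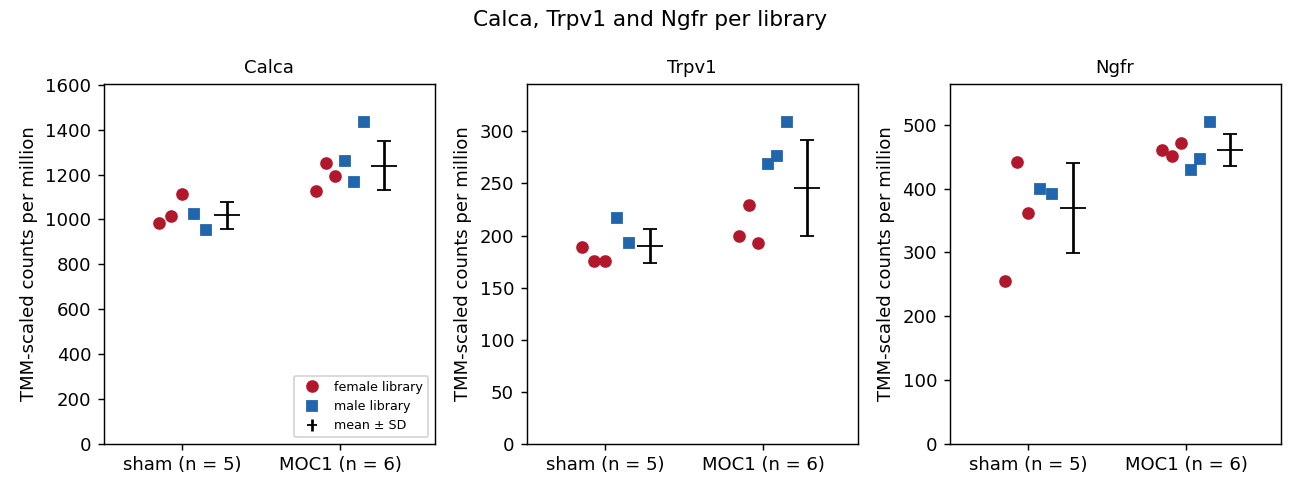
TMM-scaled CPM of Calca, Trpv1 and Ngfr in each library (circles female, squares male), with the mean and SD of 5 sham and 6 MOC1 libraries. Means are 1019 and 1240 for Calca, 190 and 246 for Trpv1, and 370 and 461 for Ngfr.

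The same comparison was made in each sex. In females 753 genes differed, 224 higher and 529 lower, and in males 211, with 28 higher and 183 lower. Pappa rose in females (2.57 ± 0.31) and males (2.75 ± 0.37), as did Alkal2 (1.93 ± 0.27 and 2.20 ± 0.31), Fstl1 (0.50 and 0.52) and Trpa1 (0.63 ± 0.10 and 1.10 ± 0.12). Il31ra (2.05 ± 0.23) and Vgf (1.20 ± 0.18) were among the leading genes of females, while Il31ra did not pass in males (0.57 ± 0.25, adjusted p = 0.552), and Cacna2d1 (0.65 ± 0.10) among those of males. Calca (0.20 ± 0.09 in females and 0.38 ± 0.10 in males), Trpv1 (0.20 ± 0.10 and 0.48 ± 0.12) and Ngfr (0.39 ± 0.14 and 0.22 ± 0.16) passed in neither sex. Their adjusted p values in females and males were 0.258 and 0.0918 for Calca, 0.328 and 0.0525 for Trpv1, and 0.137 and 0.847 for Ngfr. Hspa1a fell by 3.25 (SE 0.24) and Hspa1b by 3.24 (SE 0.27) in females, with Adamts1 (-1.82 ± 0.18), Klf6 (-1.68 ± 0.16) and Zfp36 (-1.68 ± 0.18). In males the leading losses were Col28a1 (-1.28), Nid1 (-1.48), Igfbp4 (-1.49), Nr4a1 (-1.17 ± 0.14) and Sorcs1 (-1.29 ± 0.16). The satellite glia list had a median of -1.21 in females and -1.05 in males (camera adjusted p = 2.16e-27 and 4.00e-32, adjusted p = 0.049 and adjusted p = 0.0598 with an estimated correlation). The immediate-early list had medians of -1.41 and -0.91 (camera adjusted p = 2.26e-24 and 5.56e-21, adjusted p = 0.0409 and adjusted p = 0.0708 with an estimated correlation). All 175 genes called in females and in males shared their sign. If every gene were equally likely to be called in each sex, 6.13 would overlap in the same direction. Both comparisons came from 1 fit with a shared spread, so that number may be too low. Across genes, which are not independent replicates, the log2 changes of females and males correlated with a Pearson r of 0.0731 and a Spearman rho of 0.242 over all genes tested, and with a Pearson r of 0.586 over the 9720 genes with a mean of at least 10 CPM. The arms of the sexes share no library.

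No gene passed the test of the interaction between sex and tumour with edgeR (708 had an unadjusted p under 0.05), and DESeq2 and voom called 0, with 875 and 953 at an unadjusted p under 0.05. Hspa1a had an interaction of -1.97 ± 0.34 (adjusted p = 0.299) and Il31ra of 1.48 ± 0.33 (adjusted p = 0.913). By camera 14 lists differed between the sexes, and 0 of them with an estimated correlation, where the smallest adjusted p was 0.154. Scaled to the pan-neuronal list, 12 genes were higher and 1465 lower in females and 5 higher and 292 lower in males. Without the second MOC1 female library 345 genes were called in females, and without the third sham male library 62 in males.

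**Figure D4:**
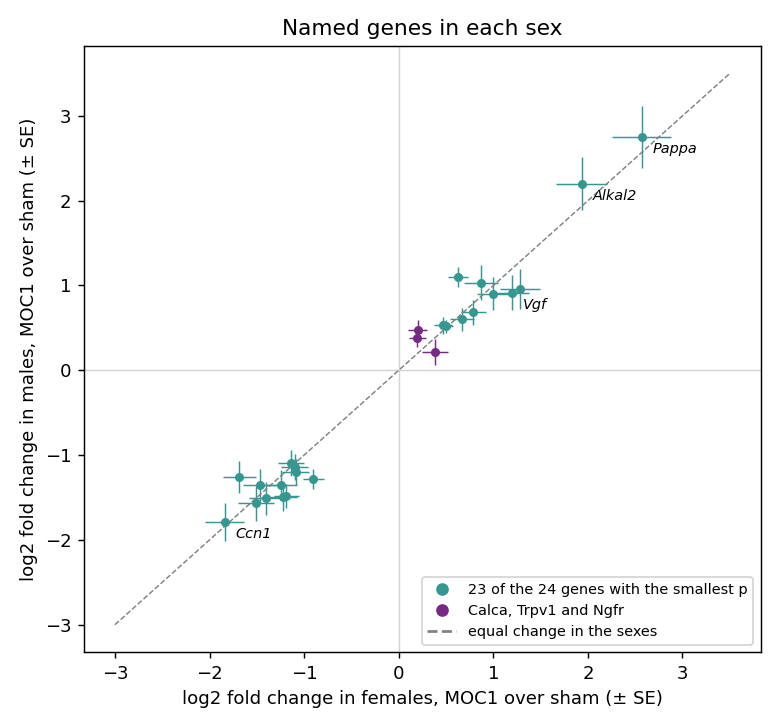
Log2 fold change of MOC1 over sham with its SE in females (horizontal) and in males (vertical) for 23 of the 24 genes with the smallest p (green) and for Calca, Trpv1 and Ngfr (purple), with a dashed line of equal change. Pappa lies at 2.57 and 2.75 and Ccn1 at -1.84 and -1.79.

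Females and males were compared with condition in the model, which checks the sex labels. Xist, the RNA that silences an X chromosome, was higher in females (log2 11.4 ± 0.27), and the Y-linked genes Ddx3y (-10.9 ± 0.36), Eif2s3y (-12.5 ± 0.41), Kdm5d (-10.5 ± 0.47) and Uty (-10.8 ± 0.40) were lower, as the labels have it. In all 7 genes differed. The other 2 were Ddx3x, an X-linked helicase (0.44 ± 0.07), and Postn, which encodes the matrix protein periostin (1.23 ± 0.17, adjusted p = 0.00313), and they fall outside the naming rule and were chosen after their values were seen.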

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

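The tests of the glial share, of other cell types, of the risers and of neuronal scaling were chosen only after the result was seen, and the tests of depth, of leaving out libraries and of other splits were not. L1cam, Scn7a and Cdh1 were singled out after their values were seen.

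Satellite glial markers were lower in MOC1. With every library thinned to 10757400 counts the list's median was -1.06. Thinning keeps each gene's expected share of the counts, so this test cannot decide on lower depth as the cause. A lower share of satellite glial RNA in the MOC1 sorts is a candidate explanation, as all 16 markers were lower and they varied together between libraries of the same arm (mean residual correlation 0.654). Less of every non-neuronal cell type cannot be told apart, because the ratio of satellite glia to macrophage counts changed by -0.88 (log2) with a two-sided exact permutation p of 0.0584, an outcome that the criterion as written counted for this explanation although a missed threshold does not show equal change. The ratios to the fibroblast (-0.48), endothelial (-0.44), erythrocyte (-0.52) and lymphocyte (-0.36) lists had adjusted p values of 0.102, 0.495, 0.712 and 0.352 in exact permutation tests, and those to the Schwann cell (-0.93) and squamous (-1.17) lists, each at 0.00758, go against an equal loss, but the Schwann members L1cam (log2 0.22) and Scn7a (0.35) rose with TMM scaling and Cdh1 held 435 CPM of the squamous list, a baseline that could hide a loss. A sort gate for labelled neurons would remove free glia but not glia attached to neurons, and an effect of the tumour on glia stays open and untested.

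Of 20 pan-neuronal genes 11 were called higher in MOC1, and the list lost its camera call, at an adjusted p = 0.0506 with an estimated correlation. A smaller glial share of the reads could account for Calca, Trpv1 and Ngfr. Their log2 changes were 0.0036 (SE 0.077), 0.045 (SE 0.10) and 0.040 (SE 0.10) with pan-neuronal scaling. It could account for most of the 394 genes called higher too, of which 29 were still called. Pan-neuronal scaling lowered nearly every gene alike, with the median of all genes at -0.30 against -0.026 with TMM. The count of 29 therefore mostly reflects the size of the changes. Of the 12 risers with the smallest p, 10 were still called, with Pappa at 2.38 and Fstl1 at 0.23, and Robo2 (0.22) was among those that were not. These 12 were picked by their p in the same libraries. Large changes are bound to outlast such a shift, so the count cannot decide on the glial share as their whole cause. With the glial marker share as a covariate, which the arms confound, Calca stood at 0.075 (SE 0.21), Trpv1 at 0.28 (SE 0.25) and Ngfr at 0.52 (SE 0.31). Trpv1 lost its call there through the wider SE more than a smaller change, and Ngfr had no call to lose. That share sums the satellite glia and Schwann cell lists. The Schwann cell list holds Ngfr itself, so Ngfr was adjusted for a sum that includes it. The pan-neuronal scaling assumes the pan-neuronal genes themselves did not change, and a change of the neurons with the tumour stays open.

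Of 29 immediate-early genes 20 were called lower in MOC1. One library as the cause is argued against, since 18 to 22 of them were called lower without each library in turn. A smaller glial share cannot be told apart for these genes, as 2 of the 20 called, Ccn1 and Egr3, were still lower with satellite glia scaling, between the bounds set for the test. Dissociation and an effect of the tumour may each change these genes, and neither was tested.

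Among 100 splits of the 11 libraries, 2 gave as many genes as MOC1 against sham, the real one included (1113 genes, highest others 1149 and 513). That share lies under 0.05 and argues against chance, but it does not exclude chance. The split with 1149 sets the third MOC1 female library apart from the other females and so points to a structure of the samples. For females 1 of 10 splits gave as many genes, too few splits for a share under 0.05 (753 genes, highest other 0 by edgeR). For females against males 3 of 100 splits gave as many, the real one included (7 genes, highest others 99 and 59). That share also lies under 0.05 without excluding chance, and the split with 99 points to a structure of the samples.

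Of 390 checks for a library far from the rest of its arm, 40 stood out, where chance gives about 1 in 20. In sham female 1 the endothelial and mural share was 1828 CPM (others 288 to 481) and the neutrophil and mast cell share 108 CPM (others 1.74 to 10.7). The same library had high CPM of Apod (68.8), Calcrl (46.1), Cldn5 (89.3), Emcn (86.0), Ltf (20.1), Lyz2 (30.7), Mal (321), S100a8 (17.5) and Tek (71.0). Sham female 2 had high CPM of Dnajb1 (613), Fos (1298), Hsp90b1 (776), Igfbp4 (265), Jun (1113) and Socs3 (314) and low CPM of Fgf13 (728). Sham female 3 had low Cacna1b (210) and high Cyp51 (271) and Ndufa9 (90.7). Sham male 1 had the lowest total of its arm (15510600 counts), high Bdnf (66.7) and Nts (34.6) and low Oprm1 (22.8), and sham male 3 had high Col1a2 (116). MOC1 male 1 had high Pappa (47.4), Trpa1 (553) and Nptx2 (213) and low Cntnap2 (248). MOC1 female 3 had high Onecut2 (177) and Ltf (3.97), a high share of interferon-stimulated genes (1197) and a low share of Schwann cell markers (3649). MOC1 female 1 had high Bgn (23.7) and Cnr1 (74.4), MOC1 female 2 high Lum (5.33), and MOC1 male 2 high Nppb (13.2) and Nts (26.2) and low Tap1 (6.51).

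By camera 14 lists differed between the sexes in their response, and 0 with an estimated correlation in limma (smallest adjusted p 0.154). By voom, median differences of female minus male log2 change were -0.25 for peptidergic and 0.20 for nonpeptidergic nociceptor genes, 0.30 for myelinated neuron genes, 0.090 for pan-neuronal genes and -0.87 for the CGRP family. They were 0.095 for potassium channels, 0.12 for ligand-gated channels, 0.092 for synaptic vesicle genes, -0.51 for immediate-early genes, -0.35 for interferon-stimulated genes and -0.38 for MHC class I genes. Satellite glia markers gave -0.24, macrophage markers -1.36 and erythrocyte markers 7.06. The last is over 5 genes with uneven libraries (Hbb-bs from 0.131 to 132 CPM), for which edgeR gave 4.22 ± 1.47 in Hbb-bs and 3.86 ± 1.71 in Alas2.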

How the results depend on the processing

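The tests with pan-neuronal scaling, satellite glia scaling and 3 libraries left out were chosen only after the result was seen. For 161 entries, each a named gene in 1 comparison, 3982 values under other settings were set against the main fit. Of these, 3609 kept the side of the threshold, 232 lost the call and 89 gained it in the same direction. The other 52 changed sign with a call in at least 1 of the 2 fits. Changes of sign without a call in either fit are counted among the 3609. MOC1 vs sham gave 1113 genes, and 1654 with DESeq2, 1116 with its size factors, 1573 with no filter, 1163 with the stricter filter, 1405 with voom, 1196 without sex, 1036 with a surrogate variable, 1076 with total counts, 1110 without mitochondrial, haemoglobin and ribosomal genes and 1245 without the 3 libraries. It gave 0 with the glial marker share as a covariate in edgeR (1151 at an unadjusted p under 0.05), which differs between the arms without overlap, 2124 with pan-neuronal and 10098 with satellite glia scaling. In females DESeq2 called 1362, no filter 1316, pan-neuronal scaling 1477 and satellite glia scaling 9013. In males DESeq2 called 391, no filter 469, voom 545, satellite glia scaling 6859 and the fit without the 3 libraries 490. The interaction gave 53 with no filter and 5 without the 3 libraries. Female vs male gave 27 with DESeq2, 73 with no filter and 29 without the 3 libraries. Of 39 lists 23 passed camera, 7 with an estimated correlation and 18 with fry. Pan-neuronal scaling moved the median of all genes to -0.30 and satellite glia scaling to 1.08. The cause of the other shifts was not tested.

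Without each library in turn, MOC1 vs sham gave 816 to 1129 genes, female vs male 6 to 9, the lists 20 to 25 and the interaction 0 to 2 in edgeR, with 2 without the first MOC1 female or the first sham female. Females gave 345 to 876, with 345 without MOC1 female 2, 448 without MOC1 female 3 and 411 without sham female 2. Males gave 62 to 340, with 99 without MOC1 male 1, 81 without MOC1 male 3, 91 without sham male 1, 62 without sham male 3 and 340 without MOC1 female 3. Where sham males are left with 1 library, it is assumed to vary like the other groups. Calca lay between 0.24 and 0.32, Trpv1 between 0.27 and 0.36 and Ngfr between 0.21 and 0.40.

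Without the 3 libraries (sham female 1, MOC1 female 3 and MOC1 male 2) the edgeR medians of 5 lists changed sign. They went from -0.060 to 0.036 for axon injury, -0.049 to 0.094 for axon guidance, -0.12 to 0.10 for macrophage, -1.85 to 0.75 for neutrophil and mast cell and -0.36 to 0.25 for fibroblast genes. The cause was not tested.

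The replicate numbers gave no sign of pairing the samples, but groups of 2 or 3 libraries are too small to exclude it. Deviations of same-numbered libraries correlated at -0.02, -0.02 and -0.01 in females and -0.01 and 0.06 in males. With the replicate block within sex 1036 genes were called, and 1090 with the number alone. Trpv1 was 0.32 with the replicate block (adjusted p = 0.0599). For female vs male the block within sex was not run, since it contains sex.

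Trpv1 was 0.28 with the glial covariate and 0.045 with pan-neuronal scaling, and Calca 0.075 and 0.0036, without a call. The SE of Trpv1 was 0.25 with the covariate and 0.08 without it. Ngfr passed with DESeq2 (0.31), no filter (0.32) and satellite glia scaling (1.44). DESeq2 made 44 false calls in the simulated MOC1 against sham comparison. The sign changes listed next are those with a call in at least 1 of the 2 fits. Signs changed with satellite glia scaling for Col28a1 (0.037), Gpm6a (0.58), Ntrk2 (0.28), Sort1 (0.62), Jun (0.030), Atf3 (0.15), P2rx7 (0.11), Efnb1 (0.21), Nr4a1 (0.11), Gbp3 (0.0059), B2m (0.30), Calr (0.82), Tap1 (0.31), Ppp1r15a (0.18), Hspa5 (0.69), Hsp90b1 (0.74), Atp5e (0.77), mt-Nd2 (0.64), mt-Cytb (0.73), mt-Nd4 (0.76), mt-Co1 (0.85), Rpl41 (0.75), Rplp1 (0.81), Rplp0 (0.94), Cyp51 (0.34), Hmgcs1 (0.70), Msmo1 (0.65), Insig1 (0.36), Cnp (0.58), Mal (0.18), Aqp4 (0.70) and Slc1a2 (0.83). They changed with the glial covariate for the gene Scn9a (-0.0058) and for Ntrk2 (0.43), Jun (0.069), Fgf13 (-0.013), Kcnj10 (0.73), Cacna1b (-0.041), Bsn (-0.39), Sema4f (-0.13), Il1rap (0.53), Irf1 (0.11), H2-Q4 (0.39), Phgdh (1.26), Cryab (0.24), mt-Nd2 (0.018), mt-Cytb (0.30), mt-Nd4 (0.24) and Insig1 (0.063), and with pan-neuronal scaling for Piezo2 (-0.017), Fgf13 (-0.036) and Gabbr1 (-0.010). Satellite glia scaling raised nearly every gene alike, with the median of all genes at 1.08 against -0.026 with TMM. Genes that fell by less than this shift change sign by it. Pan-neuronal scaling moved the median to -0.30 in the same way. The cause of the changes with the covariate was not tested. With every library thinned to 10757400 counts, 1113 genes were called, 397 higher and 716 lower, 1067 of them called in the same direction without thinning, so depth between these totals did not limit the count.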

Other observations

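The tests of pan-neuronal and satellite glia scaling and of the itch markers were chosen only after the result was seen, and so were the genes named in the next paragraph and the itch markers beside Il31ra, Osmr and Cysltr2.

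Of the genes called higher in MOC1, 29 were still called with the libraries scaled to the pan-neuronal list, and they are not a fixed gene group. Beside those already described they include the kinase Stk32a (log2 0.94 ± 0.18, adjusted p = 0.00232), Crtac1 (0.63 ± 0.13), the transcription factor Sp6 (1.87 ± 0.39), Rasef (1.00 ± 0.24), the vasopressin receptor Avpr1a (1.29 ± 0.37) and the secretory granule protein Resp18 (0.66 ± 0.18), by edgeR. With satellite glia scaling 49 genes were lower, among them Hspa1a (-1.34 ± 0.26), Hspa1b (-1.32 ± 0.27), Ccn1 (-0.73 ± 0.18), Egr3 (-0.96 ± 0.32), Cxcl10 (-0.74 ± 0.23) and the matrix proteins Reln (-0.71 ± 0.24) and Bgn (-0.63 ± 0.22).

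Xist was lower in MOC1 than in sham females, at 342 ± 60.1 against 576 ± 109 CPM (SD, n = 3 each), with a log2 change of -0.75 ± 0.18 and an edgeR adjusted p of 0.0228.

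A hypothesis is that the labelled MOC1 neurons may include more itch-type neurons, since Il31ra and Osmr were still called higher with pan-neuronal scaling (log2 1.08 and 0.48). With TMM scaling Il31ra rose by 2.05 ± 0.23 in females and did not pass in males (0.57 ± 0.25, edgeR adjusted p = 0.552), and the interaction between sex and tumour did not pass (adjusted p = 0.913). Il31ra ranged from 7.88 to 52.9 CPM in sham and from 40.5 to 74.2 CPM in MOC1 libraries. Male libraries of both arms lay at 46.1 CPM or above, so sham males lay within the MOC1 range. Osmr stood at 0.76 ± 0.18 in females (adjusted p = 0.0228) and 0.78 ± 0.21 in males (adjusted p = 0.0881). With pan-neuronal scaling Cysltr2 (0.73 ± 0.29, edgeR adjusted p = 0.114), Mrgpra3 (-0.73 ± 0.34, adjusted p = 0.168) and Mrgprx1 (-0.44 ± 0.21, adjusted p = 0.195) did not pass, and the Mrgpra3 and Mrgprx1 values, genes of another itch class, lie on the other side of 0. The summed counts of Nppb, Sst, Nts and Htr1f, other genes of such neurons, differed by 0.93 on the log2 scale with pan-neuronal scaling (SE 0.70, two-sided exact permutation p = 0.175). The spread leaves the hypothesis open.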
